A study of Mus musculus with 6 samples.

How the data were processed

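Cochlear RNA from 6 groups of female C57BL/6 mice aged 6 weeks was hybridised to 6 one-colour Agilent arrays, 1 per group, per the labels. Whether the RNA of the 6 mice of a group was pooled is not given in the sources used here. Per the labels' protocols, RNA was purified on silica columns and labelled with Cy3. The deposited scanner files hold intensity values on a linear scale, and per the file headers the authors extracted them with Agilent Feature Extraction 10.10.1.1, which subtracted background, removed spatial trends and replaced the lowest signals with surrogate values. The file headers also give the probe positions on mm9. The deposited series matrix holds log2 values of the same arrays, and how it was made is not stated. Compared with the scanner values, each of its columns equalled the log2 processed signal minus a constant for 100% of probes, within 0.001. Its column medians were -2.952 (baseline), -2.979 (noise only), -2.85 (saline 12 h), -2.81 (dexamethasone 12 h), -2.928 (saline 24 h) and -2.899 (dexamethasone 24 h). Scale, centring and direction were thus found from the values, and none of them stays unknown.

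Each array had 59305 non-control spots and 3671 control spots, and no spot was saturated. Spots marked as outliers were left out, log2 of the processed signal was taken and each array's 75th percentile over non-control probes was subtracted, and the spots of one probe were averaged. Of 56605 probes, 32994 were named through a RefSeq accession in a reference table of GRCm38.p6, used for names only, which changed 1535 names, 23611 kept the name in the file and 16 were left out for an outlier spot or no name. This gave 37318 genes, of which 11804 had more than 1 probe. A gene was represented by the probe with the highest mean over the 6 arrays. Among genes at least 2-fold apart, the text gives how often the other probes had the same direction. The median SD of log2 signal over probes spotted 10 times was 0.0353 to 0.0382 per array. The spot error of the software, dominated by a preset multiplicative error of 10%, gave the intervals at 1.96 errors, and the number of arrays limits the precision.

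A gene was called measured in a comparison when it was well above background on both arrays. A gene above background on 1 array was given as at least N-fold, against the higher of the lowest signal well above background on the dim array and its own signal there. The groups, comparisons, tests, 31 gene lists, rule for named genes and all alternatives not stated to be later were fixed before the data were examined, and 13 lists and the alternatives with spike-in scaling and without genes of neighbouring tissues were added after the data were seen. The named genes were the 10 highest and 10 lowest of each comparison among measured genes at or above the median signal, up to 4 members of each list by size, and Fos, Egr1, Atf3, Junb, Il6 and Ccl2 for noise and Fkbp5, Tsc22d3, Per1, Zbtb16 and Sgk1 for dexamethasone, with clone and accession names left out. Some list members that this rule names are not reported here. Over both times, genes were ranked by the smaller of the 2 differences. List medians were set among 10000 random lists matched in 10 bins of mean signal, with intervals from 2000 bootstrap resamples of the genes.

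Dexamethasone over both times was tested with limma 3.58.1 (lmFit, then eBayes with trend) in R 4.3.3 on 4 arrays, for genes well above background on at least 2 of them, with Benjamini-Hochberg adjustment. On simulated data for this comparison over 24767 genes, the test recovered 3% of 100 genes changed 2-fold and 73% of 100 changed 4-fold, with 4 false calls. The list percentile was tested on simulated data for dexamethasone at 12 h over 24179 genes, where 4% of 100 unshifted lists of 20 genes and 100% of 100 lists shifted by 0.5 lay outside the central 95%. The alternatives were quantile normalization, normexp background correction with an offset of 50 followed by quantile normalization, the percentile over probes detected on all arrays, the series matrix values, other filters on dim probes, the mean over a gene's probes, thresholds of 1.5-fold and 3-fold, other settings of the fit, each array left out in turn together with the time term, and scaling on the E1A spike-in probes. Other steps used data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Slide was not fitted as a block, because 4 of the 5 comparisons lie within a slide and in the limma fit it is the time term. Control probes were used in the normexp fit and for spike-in scaling only.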

Results

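Cochlear RNA of female C57BL/6 mice was measured on 6 one-colour gene expression arrays, 1 for each of 6 groups. The groups were a baseline without noise or injection, mice exposed to noise for 2 h without an injection, and noise-exposed mice sampled 12 h or 24 h after an intraperitoneal injection of saline or of dexamethasone, a synthetic glucocorticoid, at 10 mg/kg. The design text gives 6 mice per group, and the labels give no time after noise for the noise-only group. Of 56605 probes, between 63.0% (saline 24 h) and 70.3% (saline 12 h) were well above background, and the 75th percentile of the signal lay between 537 and 679 units. With 1 array per group no difference between groups had a replicate check, so no p-value is given for a comparison of 2 arrays, and the interval after a fold covers spot error only. Percentiles after a list median place it among the medians of 10000 random gene lists of the same size and matched expression, and since many fixed lists lie outside the central 95% in every comparison, a percentile of 0 or 100 is no rare event. Both 12 h arrays lay on one slide and the other 4 arrays on another. Xist, transcribed from the inactive X chromosome, was well above background on 6 of 6 arrays. The Y-linked Ddx3y and Eif2s3y were so on 0 of 6, Uty on 1 of 6, and the single probe used for Kdm5d on 6 of 6.

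After noise alone, genes of the antiviral interferon response, several chemokine genes and most genes of the circadian clock were higher than in the baseline cochlea. Genes of blood-forming marrow, dividing cells and bone-forming cells were lower. Hair cell genes were slightly higher and spiral ganglion neuron genes lay close to baseline. Interferon response genes, which cells switch on in antiviral defence, were higher after noise, with a median log2 difference of 1.54 (95% bootstrap interval over genes 1.04 to 1.90, percentile 100), and 18 of 25 measured members were at least 2-fold higher. Ifit3 was 9.83-fold (7.45 to 13.0) higher, Ifit1 6.57-fold and the GTPase gene Mx1 6.52-fold, and since every other array came from noise-exposed mice a low baseline array would look the same. The chemokine genes Cxcl10, Ccl2 and Ccl7, which attract T cells and monocytes, were 18.5-fold (14.0 to 24.4), 8.92-fold (6.75 to 11.8) and 7.94-fold higher, and the Cxcl10 probe lies on chromosome 5, 92775781 to 92775840 in mm9. The whole cytokine and chemokine list had a median of 0.16 (percentile 99.2), and the median of cytokines and chemokines, noise only against baseline, was -0.016 among genes brighter than the median. Clock genes had a median of 0.91 (percentile 100), with the transcription factor gene Dbp 4.73-fold, Per2 4.63-fold and Ciart 4.26-fold higher. Of 19 measured members 3 were lower, with Arntl at a log2 difference of -0.847. The sample details used here give no hour of day, so its part in the clock differences between arrays was not tested.

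Immediate early genes, the rapid transcriptional response to stimulation, had a median of 0.17 (percentile 99.9) in the noise-only array. Egr4 was 7.39-fold higher, the stress-induced Atf3 3.75-fold (2.84 to 4.96), Fos 1.87-fold, Egr1 1.71-fold and Junb 1.26-fold, and Il6 was not well above background on either array. Hair cell genes had a median of 0.27 (percentile 100), with Ush1c, which encodes a scaffold protein of the hair bundle, 2.00-fold higher, and stria vascularis genes one of 0.16 (percentile 99.8). Spiral ganglion neuron genes had a median of -0.10 (percentile 4.18). The antioxidant list had a median of -0.03 (percentile 38.8), while its member Hmox1, a haem-degrading enzyme, was 15.1-fold lower.

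Genes of blood and marrow cells were lower in the noise-only array. The list medians were -1.14 (percentile 0) for neutrophils and their precursors, -1.26 (percentile 0) for B cells and their precursors, -0.83 (percentile 0) for T and NK cells, -0.73 (percentile 0) for erythroid cells and -0.37 (percentile 0) for macrophages and monocytes. Vpreb1, part of the pre-B cell receptor, was 9.73-fold lower. Proliferation genes had a median of -0.93 (percentile 0), with 11 of 26 at least 2-fold lower, and genes of bone-forming cells, which line the same marrow spaces, had one of -0.80 (percentile 0), with Panx3 5.31-fold lower. Antigen presentation genes had a median of -0.57 (percentile 0) and collagen and matrix genes one of -0.52 (percentile 0).

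Genes of tissues beside the cochlea differed in the same comparison, and the lists named here for cerebellum, epidermis, sympathetic neurons, choroid plexus and pituitary were written after the data were seen. Cerebellar genes had a median of 2.85, with the Purkinje cell gene Pcp2 31.2-fold (23.7 to 41.2), and the granule cell gene Gabra6 9.45-fold higher, and En2 had a log2 difference of 4.17. Epidermal genes had a median of -2.42, with Lor, a protein of the cornified layer, 33.4-fold lower. The noradrenaline enzyme gene Dbh was 91.1-fold (68.4 to 121) lower, the choroid plexus gene Ttr 42.2-fold and the pituitary hormone gene Prl 6.42-fold. Skeletal muscle genes, a list fixed in advance, had a median of 0.73 (percentile 100). Of 24161 genes measured on both arrays, 638 were at least 2-fold higher and 768 at least 2-fold lower, 1406 in all, and a further 127 and 259 measured on 1 of the arrays were so by their lower bound. Of 327 such genes with other measured probes, 87.5% had all of those probes in the same direction. The number of genes 2-fold apart, noise only against baseline (any direction), was 686 after normexp background correction with quantile normalization, 430 among genes brighter than the median and 3457 without a filter on dim probes, and scaling on spike-in probes gave 531 higher and 988 lower. Of the 31 lists fixed in advance, 11 lay above and 11 below the central 95% of random lists. Among the lists described here, the medians that moved over 1.5 times with spike-in scaling were 0.05 for cytokine, 0.058 for immediate early, 0.16 for hair cell, 0.056 for stria vascularis, -0.21 for spiral ganglion neuron and -0.14 for antioxidant genes.

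In noise-exposed mice 12 h after saline, interferon genes were higher than at baseline. Chemokine and immediate early genes were so relative to all genes, though their list medians changed sign with spike-in scaling (-0.10 and -0.32). Genes of spiral ganglion neurons and of Schwann cells and myelin were lower, while genes of cerebellum, skeletal muscle and glands were higher. The 2 arrays lie on different slides, so slide and group cannot be told apart. Interferon genes had a median of 1.09 (0.84 to 1.33) at percentile 100, 0.27 with spike-in scaling, and 14 of 25 members were at least 2-fold higher, among them Mx2 at 4.29-fold and Ifit3 at 3.84-fold. Cytokine and chemokine genes had a median of 0.71 (percentile 100), with Ccl7 13.9-fold and Ccl2 11.9-fold (9.01 to 15.7) higher, and the median of cytokines and chemokines, saline 12 h against baseline, was 0.013 among genes brighter than the median. Il6 was measured on the saline array alone and was at least 2.75-fold higher. Immediate early genes had a median of 0.50 (percentile 100), with Egr4 3.78-fold, Atf3 2.76-fold, Fos 1.83-fold, Junb 1.73-fold and Egr1 1.19-fold higher, the last 2 lower with spike-in scaling. Adhesion and NF-kB feedback genes had a median of 0.33 (percentile 99.2), -0.49 with spike-in scaling, with the TWEAK receptor gene Tnfrsf12a 2.96-fold higher.

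Genes of the peripheral nervous system were lower in the saline 12 h array, and those of the cerebellum, in a list written after the data were seen, higher, with a median of 1.81 and 19 of 19 above baseline. Spiral ganglion neuron genes had a median of -0.66 (percentile 0), with Prph, an intermediate filament of peripheral neurons, 4.01-fold lower, and Schwann cell and myelin genes had one of -0.64 (percentile 0). A list of sensory ganglion genes, which also holds Prph and was written after the data were seen, had a median of -2.28, with the nociceptor sodium channel gene Scn10a 8.73-fold lower. Ddc and Th, of catecholamine synthesis, were 13.5-fold and 7.10-fold lower. Stria vascularis genes had a median of -0.34 (percentile 0.03) and clock genes one of -0.29 (percentile 0.53). Neutrophil genes had a median of 0.51 (percentile 100), -0.30 with spike-in scaling, and skeletal muscle genes had one of 1.68 (percentile 100), with 20 of 22 at least 2-fold higher. Mucosal and salivary gland genes, a list written after the data were seen, had a median of 4.10, with the mucin gene Muc5b 63.3-fold (48.0 to 83.5) and Tff2 43.2-fold higher, and the keratin gene Krt16 was 35.3-fold higher. Ttr was 38.1-fold lower and Pcp2 27.2-fold higher. Among 24285 genes measured on both arrays, 1072 were at least 2-fold higher and 831 at least 2-fold lower, 1903 in all, and a further 311 and 183 measured on 1 of the arrays were so by their lower bound. Of 447 such genes with other measured probes, 70.7% had all of those probes in the same direction. The number of genes 2-fold apart, saline 12 h against baseline (any direction), was 984 after normexp background correction with quantile normalization, 659 among genes brighter than the median and 5470 without a filter on dim probes, and scaling on spike-in probes gave 222 higher and 7447 lower. Quantile normalization gave 875 higher and 1037 lower. Of the 31 lists fixed in advance, 7 lay above and 7 below the central 95% of random lists. Among the lists described here, the medians that moved over 1.5 times with spike-in scaling were 0.27 for interferon, 1.00 for cerebellar, -1.48 for spiral ganglion neuron, -1.46 for Schwann cell, -1.16 for stria vascularis, -1.10 for clock and 0.86 for skeletal muscle genes.

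In noise-exposed mice 24 h after saline, interferon, chemokine and most clock genes were higher than at baseline, as in the noise-only array. Hair cell genes were higher and spiral ganglion neuron genes lower. Both arrays lie on one slide. Interferon genes had a median of 1.64 (1.12 to 1.90) at percentile 100, with 19 of 25 at least 2-fold higher, among them Ifit3 at 10.2-fold (7.73 to 13.5) and Ifit1 at 7.02-fold. Cytokine and chemokine genes had a median of 0.38 (percentile 100), with Cxcl10 12.3-fold, Ccl12 5.23-fold and Ccl2 5.54-fold higher, and Il6 not well above background on either array. Clock genes had a median of 0.81 (percentile 100), with Per2 4.98-fold, Dbp 4.45-fold and Ciart 4.32-fold higher. Of 19 measured members 3 were lower, with Arntl at a log2 difference of -1.604. Atf3 was 4.28-fold (3.23 to 5.65) higher, Egr1 1.59-fold, Junb 1.36-fold and Fos 1.18-fold, the last lower with spike-in scaling, and the immediate early list had a median of 0.23 (percentile 100), -0.063 with that scaling. Hair cell genes had a median of 0.51 (percentile 100), with Ush1c 2.27-fold higher, and stria vascularis genes one of 0.26 (percentile 100), -0.041 with spike-in scaling, while spiral ganglion neuron genes had one of -0.28 (percentile 0), with Prph 4.27-fold lower.

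Neutrophil genes were lower in the saline 24 h array, with a median of -0.68 (percentile 0), and B cell genes had one of -0.46 (percentile 0). Proliferation, erythroid and macrophage genes lay near baseline relative to all genes, with medians of -0.03 (percentile 18.5), -0.02 (percentile 27) and -0.00054 (percentile 39.2). Hmox1 was 13.4-fold lower, and skeletal muscle genes had a median of 0.92 (percentile 100). Prl was 19.3-fold, Ttr 30.2-fold, and the catecholamine enzyme genes Ddc and Th 9.95-fold and 7.83-fold lower, Pcp2 was 4.07-fold higher, and the sensory ganglion list had a median of -1.71. Of 22966 genes measured on both arrays, 396 were at least 2-fold higher and 394 at least 2-fold lower, 790 in all, and a further 335 and 170 measured on 1 of the arrays were so by their lower bound. Of 130 such genes with other measured probes, 83.1% had all of those probes in the same direction. The number of genes 2-fold apart, saline 24 h against baseline (any direction), was 415 after normexp background correction with quantile normalization, 192 among genes brighter than the median and 2896 without a filter on dim probes, and scaling on spike-in probes gave 230 higher and 860 lower. Of the 31 lists fixed in advance, 10 lay above and 9 below the central 95% of random lists. Among the lists described here, the medians that moved over 1.5 times with spike-in scaling were 0.079 for cytokine, 0.51 for clock, 0.21 for hair cell, -0.57 for spiral ganglion neuron, -0.76 for B cell, -0.33 for proliferation, -0.32 for erythroid and -0.30 for macrophage genes. The 3 comparisons with baseline share its array, so part of any likeness between them may come from that array.

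**Figure D1:**
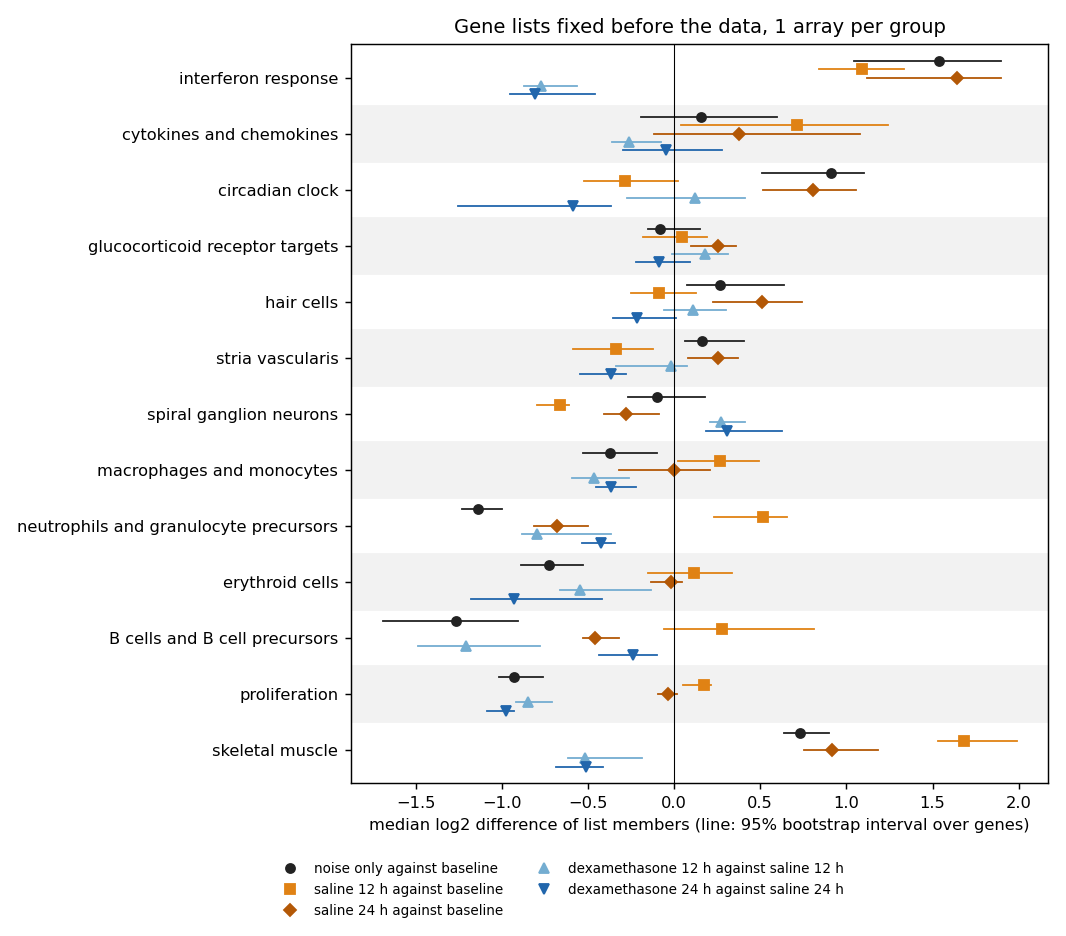
Median log2 difference of the members of 13 gene lists fixed in advance (vertical axis) in 5 comparisons with 1 array per group, where marks are medians and lines 95% bootstrap intervals over genes. Interferon genes lie at 1.54, 1.09 and 1.64 against baseline and at -0.77 and -0.81 for dexamethasone against saline.

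At 12 h, dexamethasone-treated cochleae had lower interferon, antigen presentation, leukocyte and proliferation genes than saline-treated ones. Glucocorticoid receptor targets and synaptic genes were slightly higher, and sensory ganglion genes higher by more. Both arrays lie on one slide. Interferon genes had a median, dexamethasone minus saline, of -0.77 (-0.87 to -0.56) at percentile 0 and 25 of 25 members below the saline value, among them the nucleic acid sensor gene Zbp1, 2.73-fold lower, and the regulator Irf7, 2.46-fold lower. B cell genes had a median of -1.21 (percentile 0), with Igll1 9.36-fold and Vpreb1 6.94-fold lower. Antigen presentation genes had a median of -0.94 (percentile 0), with H2-Ab1 2.74-fold lower, neutrophil genes one of -0.79 (percentile 0) and macrophage genes one of -0.47 (percentile 0). Proliferation genes had a median of -0.85 (percentile 0), with 26 of 26 members lower, and genes of bone-forming cells one of -0.60 (percentile 0), with the osteocalcin gene Bglap 3.87-fold lower. Erythroid genes had a median of -0.55 (percentile 0), -0.26 with spike-in scaling. Whether the dexamethasone samples held less bone marrow was not tested for these lists at 12 h or 24 h. The eosinophil granule genes Epx and Prg2 were 6.69-fold (5.06 to 8.83) and 6.65-fold lower, and the eosinophil list, written after the data were seen, had a median of -2.27, where the saline array itself lay at 1.92 and the dexamethasone array at -0.31 against baseline, or 1.11 and -0.84 with spike-in scaling.

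Canonical glucocorticoid receptor targets had a median of 0.18 (-0.01 to 0.31) at percentile 100, with the lipid droplet gene Plin4 2.02-fold higher. Fkbp5, a chaperone of the receptor, was 1.27-fold (0.966 to 1.68) higher, Tsc22d3 1.13-fold, the kinase gene Sgk1 1.13-fold and Per1 1.07-fold, and Zbtb16 had a log2 difference of -0.08, all within spot error, though with spike-in scaling Fkbp5, Tsc22d3 and Sgk1 lay beyond it and Zbtb16 was higher. Cytokine and chemokine genes had a median of -0.26 (percentile 0.1), 0.026 with spike-in scaling, with Cxcl9 5.96-fold lower and the B cell attractant gene Cxcl13 6.16-fold higher. The acute phase genes Serpina3m and Serpina3n were 12.7-fold and 5.75-fold higher, in a list with a median of 0.26 (percentile 99.9). The median of acute phase and metallothionein, dexamethasone 12 h against saline 12 h, was -0.033 among genes brighter than the median. Heat shock and unfolded protein genes had a median of 0.33 (percentile 100), with the chaperone gene Hspa1b 2.27-fold higher.

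Synaptic genes had a median of 0.31 (percentile 100) and spiral ganglion neuron genes one of 0.27 (percentile 100), with Prph, which is also in the sensory ganglion list, 3.05-fold higher. The nociceptor channel genes Scn10a and Scn11a were 6.23-fold (4.72 to 8.23) and 4.58-fold higher, and the sensory ganglion list had a median of 1.58. Against baseline that list had medians of -2.28 on the saline and -0.50 on the dexamethasone array, or -3.10 and -1.03 with spike-in scaling. The keratin genes Krt76 and Krt16 were 46.7-fold and 13.6-fold lower, and skeletal muscle genes had a median of -0.52 (percentile 0). Mucosal and salivary gland genes, a list written after the data were seen, had one of 1.16, with 9 of 17 at least 2-fold higher. Of 24179 genes measured on both arrays, 403 were at least 2-fold higher and 454 at least 2-fold lower, 857 in all, and a further 370 and 114 measured on 1 of the arrays were so by their lower bound. Of 138 such genes with other measured probes, 89.1% had all of those probes in the same direction. The number of genes 2-fold apart, dexamethasone 12 h against saline 12 h (any direction), was 393 after normexp background correction with quantile normalization, 237 among genes brighter than the median and 3612 without a filter on dim probes, and scaling on spike-in probes gave 825 higher and 185 lower. Of the 31 lists fixed in advance, 6 lay above and 13 below the central 95% of random lists. Among the lists described here, the medians that moved over 1.5 times with spike-in scaling were -0.48 for interferon, -0.51 for neutrophil, -0.18 for macrophage, -0.56 for proliferation, -0.31 for bone-forming cell, 0.47 for receptor target, 0.55 for acute phase, 0.62 for heat shock, 0.60 for synaptic, 0.56 for spiral ganglion neuron and -0.23 for skeletal muscle genes.

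At 24 h, interferon, proliferation, erythroid and most clock genes were lower with dexamethasone than with saline. Cholesterol synthesis and sensory neuron genes were higher, and receptor targets lay close to the saline values, which lay above baseline, though not with spike-in scaling. Both arrays lie on the other slide. Interferon genes had a median of -0.81 (-0.95 to -0.46) at percentile 0, with Mx1 3.14-fold (2.38 to 4.16), Ifi44 3.04-fold and Ifit3 2.61-fold lower. Proliferation genes had a median of -0.98 (percentile 0), with 11 of 26 at least 2-fold lower and Mki67 2.36-fold lower, and erythroid genes one of -0.93 (percentile 0), with the haemoglobin chaperone gene Ahsp 2.58-fold lower. Neutrophil and macrophage genes had medians of -0.42 (percentile 0) and -0.37 (percentile 0), with the myeloid receptor gene Trem2 2.79-fold lower. Clock genes had a median of -0.59 (percentile 0), with Dbp 9.32-fold, Ciart 5.70-fold, Per2 5.05-fold and Per3 4.10-fold lower, and against baseline the list lay at 0.81 on the saline and 0.02 on the dexamethasone array, or 0.51 and -0.39 with spike-in scaling. Of 19 measured members 3 were higher, with log2 differences of 2.005 for Arntl, 1.29 for Nfil3 and 0.603 for Clock. At 12 h the clock list had a median of 0.12 (percentile 94.6), 0.41 with spike-in scaling.

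Glucocorticoid receptor targets had a median of -0.09 (percentile 7.3) at 24 h, and against baseline medians of 0.25 on the saline array, -0.043 with spike-in scaling, and 0.23 on the dexamethasone array, -0.17 with that scaling. Per1, which is both a receptor target and a clock gene, was 1.66-fold (1.26 to 2.19) lower, and Fkbp5, Tsc22d3, Zbtb16 and Sgk1 had log2 differences of -0.08, -0.31, -0.10 and 0.31. Cholesterol synthesis genes had a median of 0.55 (percentile 100), with 17 of 18 higher, while at 12 h their median was -0.03 (percentile 50.5), 0.26 with spike-in scaling. Ccl2 was 2.97-fold and Ccl7 2.62-fold higher while Cxcl10 was 2.28-fold lower, and the stress cytokine gene Gdf15 was 6.92-fold (5.25 to 9.14) higher. Stria vascularis genes had a median of -0.37 (percentile 0), hair cell genes one of -0.22 (percentile 0.12), and spiral ligament and limbus fibrocyte genes one of -0.42 (percentile 0), with the transporter gene Slc4a11 3.53-fold lower. At 12 h the same lists had medians of -0.017, 0.11 and -0.17, or 0.27, 0.40 and 0.12 with spike-in scaling.

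Spiral ganglion neuron genes had a median of 0.31 (percentile 100) at 24 h, with Prph, which is also in the sensory ganglion list, 5.68-fold higher. Scn10a was 6.97-fold higher and the sensory ganglion list had a median of 2.20, and against baseline that list had medians of -1.71 on the saline and 0.44 on the dexamethasone array, or -2.01 and 0.037 with spike-in scaling. The pituitary hormone genes Pomc and Prl were 122-fold (91.9 to 161) and 70.1-fold higher, with the Pomc probe on chromosome 12, 3960413 to 3960472 in mm9, and Ttr was 29.7-fold higher. The catecholamine enzyme genes Ddc and Th were 9.90-fold and 8.97-fold higher, Pcp2 was 2.95-fold lower, and skeletal muscle genes had a median of -0.51 (percentile 0). Of 22710 genes measured on both arrays, 371 were at least 2-fold higher and 347 at least 2-fold lower, 718 in all, and a further 260 and 278 measured on 1 of the arrays were so by their lower bound. Of 159 such genes with other measured probes, 88.1% had all of those probes in the same direction. The number of genes 2-fold apart, dexamethasone 24 h against saline 24 h (any direction), was 353 after normexp background correction with quantile normalization, 191 among genes brighter than the median and 2813 without a filter on dim probes, and scaling on spike-in probes gave 301 higher and 493 lower. Of the 31 lists fixed in advance, 8 lay above and 15 below the central 95% of random lists. Among the lists described here, the medians that moved over 1.5 times with spike-in scaling were -0.19 for receptor target and 0.20 for spiral ganglion neuron genes.

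Dexamethasone over both times was tested with limma on the 4 injected arrays, with time, which is also the slide, as an additive term. Proliferation and interferon genes held the most members past the threshold when adjusted over the list alone: 26 of 26 and 20 of 25 fell. Adjusted over the list alone, 16 of 27 neutrophil, 15 of 22 erythroid, 14 of 24 macrophage, 12 of 22 skeletal muscle, 9 of 17 antigen presentation and 5 of 21 T and NK cell genes fell, 1 macrophage gene rose, and 5 of 24 spiral ganglion neuron genes rose. The spiral ganglion neuron list shares Prph with the sensory ganglion list. Lists with fewer such genes or both directions were spiral ligament and limbus fibrocytes, with 6 of 19 lower and 1 higher, cytokines and chemokines, with 2 higher and 2 lower of 25, clock genes, with 1 and 2 of 20, and acute phase genes, with 1 and 1 of 18. A single gene passed in each of the heat shock, supporting cell and brain lists (higher) and the Schwann cell list (lower), adjusted over the list alone. Of 34 glucocorticoid receptor targets 0 passed in limma adjusted over the list alone, with 5 at an unadjusted p under 0.05, and of 22 B cell genes 0 passed, with 10 at an unadjusted p under 0.05. Of 23 hair cell, 23 stria vascularis and 18 cholesterol synthesis genes 0 passed likewise, with 4, 6 and 4 at an unadjusted p under 0.05. Adjusted over all 24767 genes tested, 0 passed an adjusted p of 0.05 in limma, so 0 members of any list passed by that adjustment. Of all genes tested, 3635 had an unadjusted p under 0.05. The number past the threshold was 951 without the filter on dim probes, 536 with scaling on spike-in probes and 0 without the time term. In the spike-in fit the prior degrees of freedom were infinite, so a gene's own spread did not enter. With 1 residual degree of freedom, these p-values measure against the difference between the effects at 12 h and 24 h, joined with a prior pooled over genes. An effect at 1 time only counts as error, so a list with 0 passing need not be unchanged. The spread lies between 4 arrays and may be technical. Members of a list share those arrays and are not independent replicates, so a count of members passing does not replicate an effect.

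The dexamethasone differences at 12 h and 24 h share no array. Among the genes named by size at both times, the sensory neuron genes Scn10a, Scn11a, Prph, Calca and Avil and the lipogenic gene Thrsp were higher at both, and the slow muscle myosin gene Myh7, Dbp, Prg2, Epx and Ahsp were lower at both. Over 22497 genes the differences correlated across genes with a Pearson r of 0.36 and a Spearman rho of 0.36, and genes are not independent replicates. At least 2-fold higher at both times were 61 genes and lower 74, where independent lists would share 4.13 and 5.59, and 10 differed in opposite directions. The 135 in the same direction were 59 after normexp with quantile normalization and 45 among genes brighter than the median, and the 10 in opposite directions were 3 under each.

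**Figure D2:**
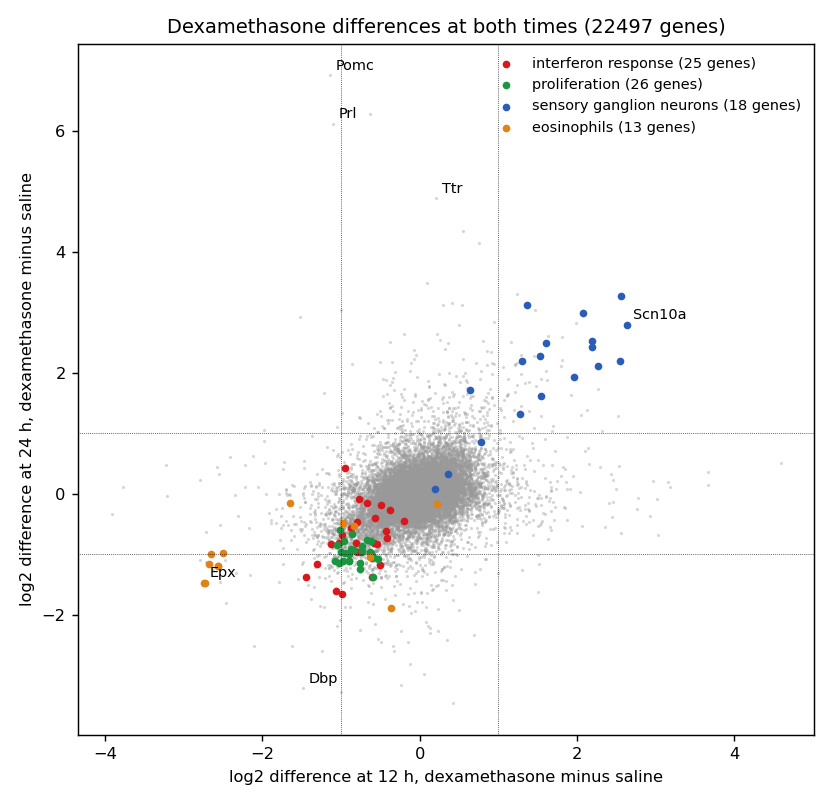
Log2 difference between dexamethasone and saline at 12 h (horizontal) and at 24 h (vertical) for 22497 genes, 1 array per group, with dotted lines at 2-fold and coloured points for 4 gene lists, of which the sensory ganglion and eosinophil lists were written after the data were seen. The sensory ganglion genes have medians of 1.58 and 2.20, and Pomc lies at -1.14 and 6.93.

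Noise and dexamethasone differences were related over 22460 genes in the 4 pairs that share no array. The noise-only difference and the dexamethasone difference at 12 h had a Pearson r of 0.31 and a Spearman rho of 0.32 across genes, and with that at 24 h the values were -0.04 and -0.002. Saline 12 h against baseline and dexamethasone at 24 h had an r of -0.36 and a rho of -0.33, and saline 24 h against baseline and dexamethasone at 12 h had -0.01 and 0.04. The B cell gene Vpreb1 was lower in the noise-only array and lower with dexamethasone at 12 h, as was the B cell list, with medians of -1.26 and -1.21. Interferon genes went opposite ways there, at 1.54 and -0.77. Prph was lower in the saline 12 h array, on another slide than baseline, and higher with dexamethasone at 24 h, as was the sensory ganglion list, at -2.28 and 2.20. What these correlations reflect was not tested.

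**Figure D3:**
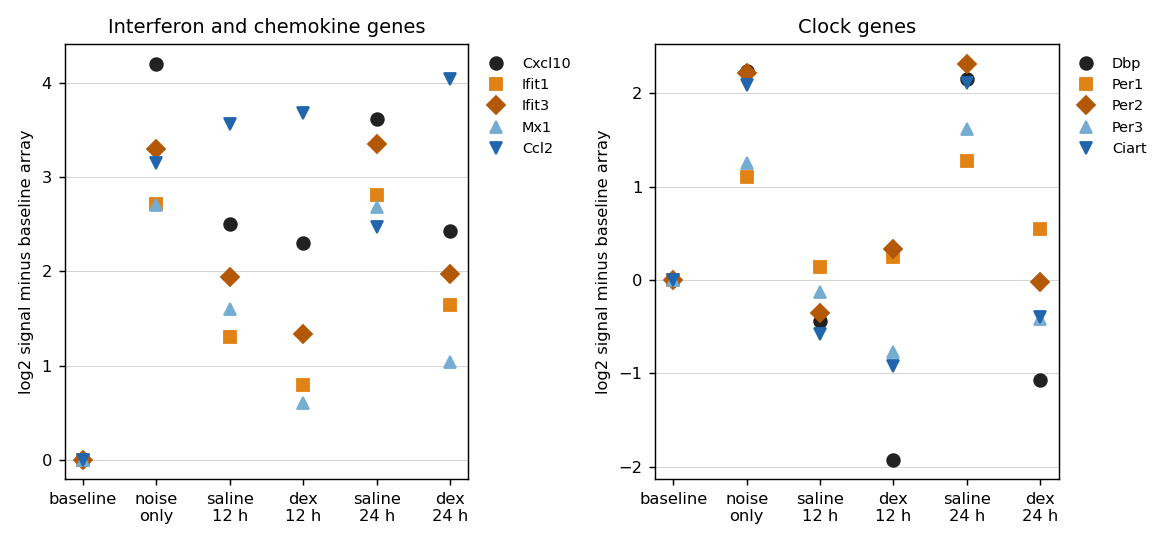
Log2 signal of each array minus that of the baseline array for 5 interferon and chemokine genes (left) and 5 clock genes (right), with 1 point per gene and array. Per2 lies at 2.21 in the noise-only and 2.31 in the saline 24 h array, and Cxcl10 at 4.21 and 3.62.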

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

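The tests of explanations in this part were chosen after the results had been seen, as were the sensory ganglion and eosinophil lists and the scaling on spike-in probes.

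Some dexamethasone differences had opposite signs at 12 h and 24 h, and with 1 array per group the difference between the times was not tested. Pomc had a log2 difference of -1.14 at 12 h and 6.93 at 24 h, and Prl -1.10 and 6.13. The median of the collagen and matrix list was -0.32 at 12 h and 0.22 at 24 h, but -0.027 and 0.11 with spike-in scaling, and that of the cerebellar list, written after the data were seen, 0.18 and -0.97, or 0.47 and -1.08 with that scaling. Pomc and Prl are pituitary genes, and markers of pituitary, cerebellum and other tissue beside the cochlea differed by large factors between arrays, so these values need not be effects of dexamethasone. Unequal dissection of such tissue was not tested.

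Genes of sensory ganglion neurons (20 genes, 19 of them above background on the baseline array and 4 in another list) were higher with dexamethasone at both times, by medians of 1.58 and 2.20, yet against baseline the saline arrays lay further away, at -2.28 and -1.71 beside -0.50 and 0.44 with dexamethasone (with spike-in scaling -3.10 and -2.01 beside -1.03 and 0.037). With spike-in scaling, the shift of all genes left in, the smaller of the 2 medians was 1.86 (1.59 to 2.48). That scaling moves every gene of a comparison by the same constant, 0.29 at 12 h and -0.11 at 24 h. The value was thus fixed by the constant and is no separate test of array scaling. Both constants are smaller in size than the list medians of 1.58 and 2.20. Among 13 members whose values had not been seen when the list was written, the median exceeded that of spiral ganglion neuron genes outside the sensory ganglion list by 1.28 (0.44 to 1.95) at 12 h, the smaller of the 2 times. This argues against more spiral ganglion tissue as the whole cause only, since the full spiral ganglion neuron list was itself higher, at 0.27 and 0.31. Of the 13 members, 13 were higher at both times. Unequal amounts of another sensory ganglion in the samples may give such a count, but the list was chosen for the direction of other members. The most abundant members, Prph and Calca, had log2 signals of 3.43 and 3.15 on the baseline array relative to its 75th percentile. An effect of dexamethasone on such neurons would give the same count and stays open and untested with 1 array per group.

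Interferon genes (25 genes, 25 of them above background on the baseline array and 0 in another list) were higher after noise and lower with dexamethasone. After noise the macrophage and neutrophil medians were -0.37 and -1.14, and the interferon median exceeded the larger by 1.91 (1.33 to 2.36). Neither list thus rose with the interferon genes. Erythroid and bone-forming cell genes were lower too, at -0.73 and -0.80, and less marrow in the sample could hide added leukocytes. More leukocytes in the noise-only sample therefore stay open. Every other array lay above baseline, the lowest being dexamethasone 12 h at 0.26, which was -0.27 with spike-in scaling, and since all of those mice had noise, an effect of noise and a low baseline array cannot be told apart. With dexamethasone the interferon median lay below the macrophage median by a difference of -0.30 (-0.54 to -0.04) at 12 h and -0.44 (-0.62 to -0.11) at 24 h. Fewer macrophages would lower each gene only by the share that macrophages contribute, so this gap does not exclude them. Other leukocytes stay open too. Neutrophil medians were -0.79 at 12 h, -0.51 with spike-in scaling, and -0.42 at 24 h, and B cell medians were -1.21 and -0.24. A lower interferon response under dexamethasone is a hypothesis that replicate arrays could test.

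Eosinophil genes (14 genes, 14 of them above background on the baseline array and 1 in another list) were lower with dexamethasone, by medians of -2.27 at 12 h and -1.04 at 24 h. These medians include members whose values had been seen when the list was written. The members not seen then, 7 at 12 h and 6 at 24 h, lay -0.035 (-1.17 to 0.45) and 0.43 (-0.55 to 0.89) from the lower of the neutrophil and erythroid medians. That lower median was -0.79 (neutrophil) at 12 h and -0.93 (erythroid) at 24 h, so these members fell by less than the full list. Less bone marrow in the sample and fewer eosinophils cannot be told apart. A high saline 24 h array stays open too, since its eosinophil median was -0.32 against baseline, -0.62 with spike-in scaling, but 1.29 (0.54 to 1.48) against the noise-only array. At 12 h the saline array lay at 1.92 and the dexamethasone array at -0.31 against baseline, or 1.11 and -0.84 with spike-in scaling, so a high saline array may explain part of that difference. The most abundant members, Ear2 and Prg2, had log2 signals of 6.02 and 5.95 on the saline 12 h array relative to its 75th percentile, and an effect of dexamethasone stays open and untested.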

How the results depend on the processing

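Scaling on spike-in probes and removal of neighbouring-tissue, muscle, bone and blood genes were chosen after seeing the data, and the other alternatives before. Values after that removal are not reported here. No paired analysis was possible because each group has 1 array and the labels give no replicate numbers to pair mice by, and the time term of the limma fit matches arrays by time only. Signal over background limits the calls: 63.0% to 70.3% of probes were well above it. After normexp with quantile normalization, among genes brighter than the median, without the filter on dim probes, at 1.5-fold and at 3-fold, and then as higher and lower with spike-in scaling, the counts were as follows. For genes 2-fold apart, noise only against baseline, they were 686, 430, 3457, 3649, 399, and 531 and 988. For genes 2-fold apart, saline 12 h against baseline, they were 984, 659, 5470, 6177, 551, and 222 and 7447. For genes 2-fold apart, saline 24 h against baseline, they were 415, 192, 2896, 2350, 265, and 230 and 860. For genes 2-fold apart, dexamethasone 12 h against saline 12 h, they were 393, 237, 3612, 3093, 251, and 825 and 185. For genes 2-fold apart, dexamethasone 24 h against saline 24 h, they were 353, 191, 2813, 2521, 206, and 301 and 493. The 1.5-fold and 3-fold counts follow from the thresholds. Spike-in scaling moved the median of all genes by -0.11, -0.82, -0.30, 0.29 and -0.11 in the same order, which a list median relative to that shift cannot show. With the shift left in, 13 of 154 list medians beyond the central 95% of random lists changed sign: at saline 12 h immediate early (-0.32), cytokine (-0.10), adhesion (-0.49), neutrophil (-0.30), antigen presentation (-0.28) and pituitary (-0.38) genes, at saline 24 h immediate early (-0.063), receptor target (-0.043), supporting cell (-0.13), stria (-0.041) and fibrocyte (-0.13) genes, and with dexamethasone at 12 h cytokine (0.026) and osteoclast (0.021) genes. Quantile normalization gave 875 higher and 1037 lower for saline 12 h, and spike-in scaling 7669 in all. The limma count for dexamethasone over both times was 951 without the filter on dim probes, with prior degrees of freedom of 10.4 against 3.73 in the reported fit and 41 of the 951 above background on under 2 of the 4 arrays, and 536 with spike-in scaling, where the prior degrees of freedom were infinite. Leaving out 1 array at a time together with the time term gave 0 to 21, with 21 without the dexamethasone 12 h array, where 4 arrays without the time term gave 0 and the lone array left in a group was assumed to vary like the others. The genes 2-fold apart the same way at both times numbered 59 after normexp with quantile normalization and 45 among brighter genes, and 3 under each went opposite ways.

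Of 1099 alternative values of 220 list medians, those with spike-in scaling not counted, 1078 lay within the bootstrap interval of the reported median, 17 moved outside it and 4 changed the sign of a median beyond the central 95% of random lists. Among genes brighter than the median, the median of cytokines and chemokines, noise only against baseline, was -0.016, the median of cytokines and chemokines, saline 12 h against baseline, 0.013, the median of acute phase and metallothionein, dexamethasone 12 h against saline 12 h, -0.033 and that of the gland list with dexamethasone -0.19 at 24 h. Over all its measured genes the gland list had a median of 0.30 in that comparison. With the mean over a gene's probes the synaptic list had 0.55 after noise and the median of brain tissue, dexamethasone 24 h against saline 24 h, was 0.00492. Quantile normalization gave 0.44 for heat shock genes with dexamethasone at 12 h and 1.44 for muscle genes at saline 12 h. Normexp with quantile normalization gave 1.44 for the latter, -0.90 for B cell genes after noise, and -0.69 and -0.93 for proliferation genes with dexamethasone at 12 h and 24 h. For these counts and medians, apart from the fold thresholds, the cause was not tested. Of 616 alternative values of 154 differences of named genes, 582 lay within spot error, 34 did not and 0 changed the sign of a difference of at least 2-fold.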

Other observations

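The lists in this part were written after the largest differences had been seen, so their counts are not independent evidence of direction, and no explanation was tested on them.

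Genes of platelets and their precursors and of replicating cells differed with dexamethasone in one direction at both times. Megakaryocyte and platelet genes had medians of -0.80 and -0.62 at 12 h and 24 h, and in limma 12 of 14 fell adjusted over the list alone and 0 over all genes tested, with 12 at an unadjusted p under 0.05. S-phase histone genes had medians of -1.04 and -0.85, and 9 of 11 fell adjusted over the list alone and 0 over all genes in limma, with 9 at an unadjusted p under 0.05. The platelet list was also lower after noise alone, at -0.94. Mast cell and basophil genes had medians of -0.59 and -0.12, and 0 of 11 passed in limma adjusted over the list alone, with 4 at an unadjusted p under 0.05.

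Adipose genes were higher with dexamethasone, with medians of 0.69 at 12 h and 1.03 at 24 h, and 11 of 17 rose adjusted over the list alone and 0 over all genes tested in limma, with 12 at an unadjusted p under 0.05. Against baseline the same list lay at -0.60 and -0.54 on the saline arrays. Sympathetic neuron genes had medians of 0.57 and 2.11 with dexamethasone and of -2.78 and -1.77 on the saline arrays against baseline. Genes of slow and cardiac-type muscle had medians of -0.96 and -0.45 with dexamethasone, and epidermal genes of -0.53 and -0.58. The pituitary list had medians of 0.03 and 1.43 and the choroid plexus list of 0.08 and 1.12. Among the medians of these lists, those that moved over 1.5 times or changed sign with spike-in scaling were -0.51 for platelet, -0.30 for mast cell, 0.86 for sympathetic neuron, -0.25 for epidermal, 0.31 for pituitary and 0.37 for choroid plexus genes with dexamethasone at 12 h, -0.23 for mast cell genes with dexamethasone at 24 h, -1.42 for adipose genes at saline 12 h against baseline, and -0.84 for adipose genes at saline 24 h against baseline.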
